A study of Mus musculus with 6 samples.

How the data were processed

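Total RNA from RAW264.7 cells was sequenced in 3 acoustics-off and 3 acoustics-on libraries. Per the labels' protocols, libraries were made with a ribosomal RNA depletion kit, while the molecule field of the same labels says polyA RNA; this conflict was left open. Per the submitters' processing notes, the tools were Trim Galore 0.6.8, STAR 2.7.11, Salmon 1.4.0 and DESeq2 1.38.2, and the genome build was GRCm38; their order and settings are not given in the sources used here. The authors deposited FPKM values per gene and library. The authors also deposited a table of their comparison, with a mean of normalised counts per gene, log2 fold changes with standard errors, a test score (the Wald statistic) and p-values with adjusted p-values. The score equalled the log2 fold change over its standard error to within 8.3e-14. An adjusted p was missing for 1586 genes in the authors' deposited table and was left missing.

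The files held no counts. A test on counts had been planned before the data were examined, with limma on log2(FPKM + 1) as the stated substitute where counts were not given, and that substitute is the test used here. Multiplying FPKM by the authors' deposited mean count over the mean FPKM gave 56.1% to 66.8% of values under 15 within 0.05 of a whole number, against 10.4% to 12.1% with another step, so relative depth was read from these steps but reads were not recovered. Genes with an FPKM of at least 0.5 in at least 3 libraries were tested. limma 3.58.1 in R 4.3.3 was used with a trended, robust variance prior, on minus off, with no replicate term and Benjamini-Hochberg adjustment at 0.05. Data were simulated over 5 draws with 200 changed genes per draw, and the lysosome and autophagy list was also shifted by 0.7. With 11689 genes tested on average, this test found 41.9% of genes changed by a log2 difference of 1 and 84.2% of those changed by 2. Of all its calls, those on the shifted list included, 5.21% were false. Genes were drawn independently, with no length trend and no outlying library, so these rates may not hold for the real data. No value was the same above 0 in any pair of libraries.

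A set of 46 gene lists was fixed before the data were examined, and 41 had at least 3 tested members. Some lists and members are not reported here. The lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. With an estimated correlation 0 lists passed. The estimate reached 0.92, for the cytosolic ribosomal protein genes, and this form was run only on the main analysis. List p-values with a library left out or with a correction use the preset correlation and have no such counterpart. The mitochondrially encoded list matched 0 symbols, since the file names these genes differently, and 0 of 4 epithelial markers passed the filter. Genes were named by a rule fixed before the data were examined: the 12 largest changes each way among genes past the threshold, with a mean log2(FPKM + 1) of at least 1 (in place of the planned mean log2 CPM), groups that did not overlap and an established symbol; 11 genes chosen in advance; and up to 4 members with the smallest p of each list. Groups did not overlap for 4054 genes (34.8%), where chance gives 10%. Coordinates came from GENCODE M21 (GRCm38), matched by symbol for 15943 genes.

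Alternatives were another pseudocount, other filters and scalings, a replicate term, each library left out, no robust prior and a fold minimum. With a library left out, the filter was set on the remaining libraries. After seeing the data, library weights and a length and GC correction were added. The correction fitted a loess trend (span 0.5) of each library on the length and GC content of the longest transcript over protein-coding genes with a mean FPKM of at least 1, and divided it out of the FPKM values. A first form, which took the trend off the log2 values, was replaced after its result had been seen because it also shifts genes near 0; both are given. Annotation lacked the newer histone symbols, so the correction says nothing on that list.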

Results

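RNA-seq was performed on RAW264.7 cells, a mouse macrophage-like cell line, that were attached to acoustic devices and cultured for 48 h with the acoustics off or on. With acoustics on, the devices were driven at 18 V peak to peak and 5 kHz. There were 3 libraries per group. A petri-dish group named in the series design was not analysed here. The deposited values were FPKM for 16108 genes, and 11664 genes passed the filter on low values. The steps of the low values, which reflect whole reads, gave relative depths between 0.96 and 1.08. At a mean FPKM of 0.5 to 1 the median gene had 51.2 normalised reads in the authors' deposited table, so counting alone gives a coefficient of variation of about 14.0%. The labels do not say whether the libraries came from separate experiments, so the p-values measure the spread between these samples, which may be technical.

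The comparison of acoustics on with acoustics off asks how the acoustic treatment is reflected in the transcripts of these cells. With acoustics on, 175 genes rose and 67 fell (limma, Benjamini-Hochberg adjusted p under 0.05). The genes that rose included targets of the oxidative stress regulator NRF2, interferon-stimulated genes and the metalloproteinase genes Mmp12 and Mmp9, and those that fell included immediate-early transcription factors and the complement and mannose receptor genes C1qa and Mrc1. The macrophage elastase gene Mmp12 (chromosome 9, 7344381 to 7369499, GRCm38) had the largest rise among the named genes, from 3.79 ± 1.30 to 195.1 ± 32.5 FPKM (SD, n = 3), with a log2 difference of 5.38 (SE 0.24, adjusted p = 0.00097). Egr1 (chromosome 18, 34859823 to 34864984), an immediate-early transcription factor, fell from 158.1 ± 32.5 to 16.4 ± 2.82 FPKM, with a log2 difference of -3.19 (SE 0.19, adjusted p = 0.0019). Fold changes here are on the log2(FPKM + 1) scale, which understates the change of low genes.

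The 12 largest rises among the named genes were in Mmp12, Pdpn, Procr, Gsta2, Cd5l, Ccl2, Hp, Ccl5, Serpinb9b, Isg15, Acod1 and Gclm, with log2 differences from 2.79 to 5.38. Pdpn, which encodes the membrane glycoprotein podoplanin, averaged 0.72 ± 0.15 FPKM with acoustics off and 27.3 ± 10.6 with acoustics on. The chemokine gene Ccl2 averaged 7.78 ± 0.60 and 98.2 ± 50.5 FPKM. Acod1, which encodes the enzyme that makes itaconate, averaged 6.47 ± 0.30 and 52.9 ± 15.7 FPKM. Gsta2 and Serpinb9b belong to families of similar genes, so reads shared with close copies leave their values uncertain. The 12 largest falls were in C1qa, Fosb, Egr1, Ccl6, Mrc1, Fos, Gpr34, Dusp1, Cytip, Zfp36l1, Cd28 and Slc9a9, with log2 differences from -3.85 to -2.06. C1qa, a chain of complement C1q, averaged 35.5 ± 10.4 FPKM with acoustics off and 2.53 ± 3.72 with acoustics on. The chemokine gene Ccl6 averaged 161.1 ± 32.5 and 20.3 ± 5.87 FPKM, and the mannose receptor gene Mrc1 averaged 43.0 ± 4.27 and 6.45 ± 6.49 FPKM.

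The number of genes past the threshold depended on single libraries. It was 26, 17 and 25 without acoustics-off replicates 1, 2 and 3, and 855 (498 higher, 357 lower), 324 (189 higher, 135 lower) and 63 without acoustics-on replicates 1, 2 and 3. The filter was set anew on the libraries that remained, so some called genes were then not tested. Without any 1 acoustics-on library, 214 of the 242 genes called were tested with the same direction. Of the 242, 214, 168 and 61 still passed without acoustics-on replicates 1, 2 and 3. Of the genes named above, Mmp12, Pdpn, Procr, Hp, Isg15, Acod1, Gclm, Egr1, Ccl6 and Cytip passed with each of the 6 libraries left out in turn. The others did not pass in all of these fits. Gsta2 and Serpinb9b were below the filter, and so not tested, without acoustics-on replicate 1. With transcript length and GC trends divided out of each library, a step chosen after seeing the data, 310 genes were higher and 358 lower.

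**Figure D1:**
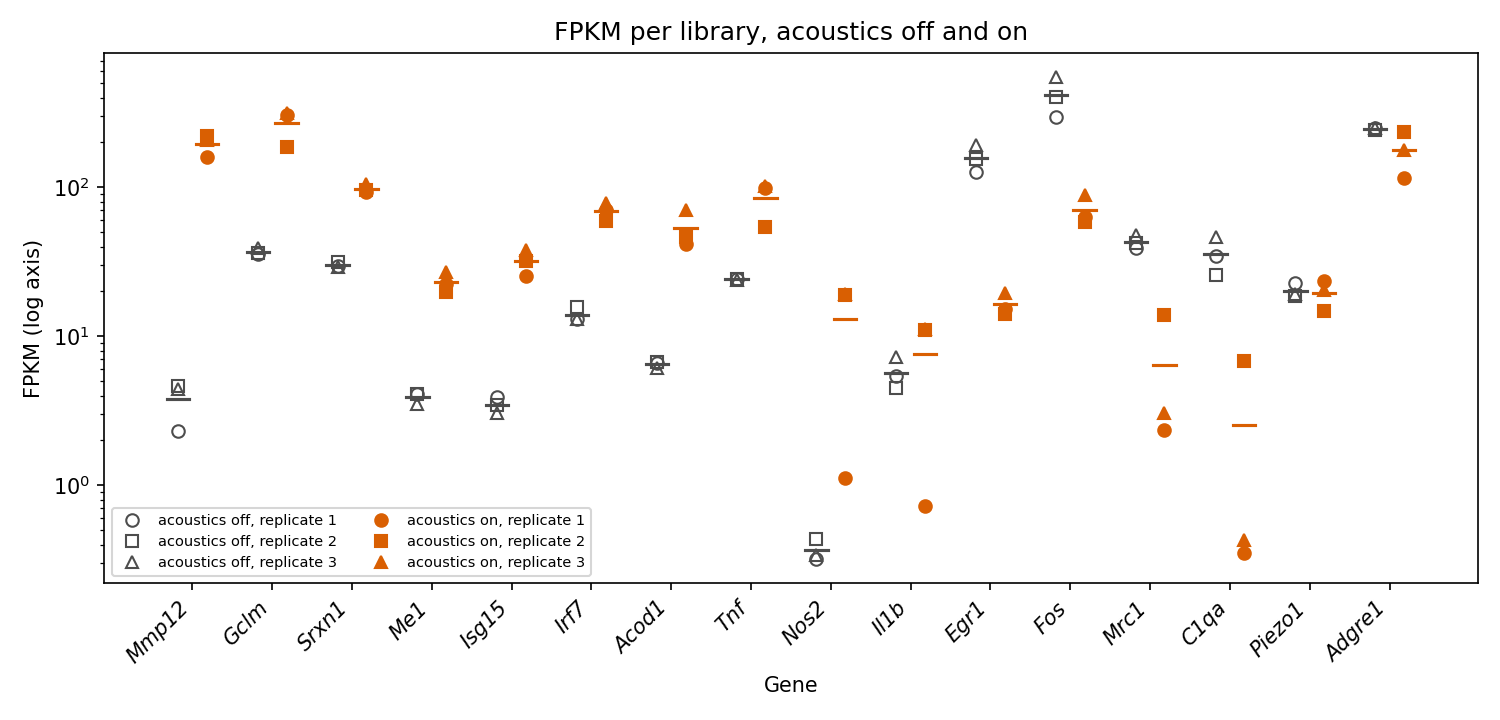
FPKM per library on a log axis for 16 genes; open grey symbols are the acoustics-off libraries, filled orange symbols the acoustics-on libraries, symbol shapes mark the replicates, and short lines mark group means. Nos2 was at 1.13 FPKM in acoustics-on replicate 1 and at 18.9 and 19.2 FPKM in replicates 2 and 3.

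NRF2 target genes, which encode antioxidant and detoxifying enzymes, ranked higher. Of 26 members tested, 14 rose and 0 fell over all genes, and 23 rose and 1 fell when adjusted over the list alone. The list's median log2 difference was 1.10 (camera, adjusted p = 3.4e-18, and adjusted p = 0.052 with an estimated correlation). Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, averaged 36.9 ± 1.77 FPKM with acoustics off and 269.2 ± 71.6 with acoustics on (log2 difference 2.79, SE 0.22, adjusted p = 0.0030). The sulfiredoxin gene Srxn1 averaged 30.2 ± 1.35 and 98.1 ± 6.69 FPKM, and the malic enzyme gene Me1 averaged 3.91 ± 0.35 and 23.1 ± 3.54 FPKM. The median was 1.28, 0.93 and 1.09 above the acoustics-off mean in acoustics-on replicates 1, 2 and 3. Without acoustics-on replicate 1, 18 members rose, while Gsta3, which had risen with all libraries, was then below the filter.

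Interferon-stimulated genes also ranked higher. Of 34 members tested, 18 rose and 0 fell over all genes, and 25 rose and 0 fell when adjusted over the list alone. The median log2 difference was 0.97 (camera, adjusted p = 2.7e-19, and adjusted p = 0.15 with an estimated correlation). Isg15, which encodes a ubiquitin-like protein, averaged 3.47 ± 0.42 FPKM with acoustics off and 31.8 ± 6.07 with acoustics on (log2 difference 2.86, SE 0.17, adjusted p = 0.0019). The transcription factor gene Irf7 averaged 13.9 ± 1.52 and 69.6 ± 9.68 FPKM. Oasl2 averaged 0.76 ± 0.15 and 4.28 ± 0.52 FPKM. The list's median was 0.92, 0.87 and 1.01 above the acoustics-off mean in acoustics-on replicates 1, 2 and 3. Without replicate 1, 18 members rose, while Ifit3, which had risen with all libraries, was then below the filter.

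Immediate-early genes, which cells transcribe within minutes of a stimulus, ranked lower. Of 32 members tested, 8 fell and 1 rose over all genes, and 12 fell and 4 rose when adjusted over the list alone. The median log2 difference was -0.36 (camera, adjusted p = 0.00012, and adjusted p = 0.49 with an estimated correlation). Fos averaged 414.8 ± 127.6 FPKM with acoustics off and 70.4 ± 16.5 with acoustics on (log2 difference -2.52, SE 0.27, adjusted p = 0.0094). Nr4a1 averaged 14.3 ± 1.66 and 3.42 ± 0.78 FPKM, and Btg2 averaged 25.3 ± 2.84 and 6.70 ± 1.4 FPKM. In acoustics-off replicates 1, 2 and 3, Fos was at 294.4, 401.3 and 548.6 FPKM, and Fosb at 7.18, 19.9 and 33.5 FPKM. Egr1 and Dusp1 also increased in that order within the acoustics-off group, while Nr4a1 and Btg2 did not. The member that rose was Fosl1, named here after its value was seen. Without acoustics-on replicate 1, 10 members fell and 3 rose.

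Genes associated with the classically activated (M1) state ranked higher. Of 19 members tested, 4 rose and 0 fell, and 10 rose and 1 fell when adjusted over the list alone. The median log2 difference was 0.59 (camera, adjusted p = 0.00033, and adjusted p = 0.49 with an estimated correlation), and 0.31 with the length and GC correction (adjusted p = 0.0035). The members that rose were Acod1, Cxcl11, Tnf and Ccl5. With the length and GC correction Ccl5 no longer passed (adjusted p = 0.073), while the other members named did. The cytokine gene Tnf (chromosome 17, 35199381 to 35202007) averaged 24.1 ± 0.31 FPKM with acoustics off and 84.9 ± 27.0 with acoustics on (log2 difference 1.72, SE 0.25, adjusted p = 0.022). Nos2, the inducible nitric oxide synthase gene, had 0.32, 0.44 and 0.34 FPKM with acoustics off and 1.13, 18.9 and 19.2 FPKM with acoustics on, and did not pass (log2 difference 2.80, SE 0.82, adjusted p = 0.15). It passed with the length and GC correction and acoustics-on replicate 1 left out, a setting chosen after seeing the data (log2 difference 3.91, adjusted p = 6.0e-05). The interleukin gene Il1b averaged 5.71 ± 1.43 and 7.61 ± 5.97 FPKM (adjusted p = 0.96), with 0.72 FPKM in acoustics-on replicate 1 and 10.99 and 11.1 FPKM in replicates 2 and 3. Without replicate 1 its log2 difference was 0.87 (adjusted p = 0.037). Il6 was listed at 0 in the acoustics-off libraries and in acoustics-on replicate 1, and at 1.16 and 1.17 FPKM in replicates 2 and 3, and was below the filter. Il10, which is on the M2 list described below, averaged 0.21 ± 0.12 and 0.99 ± 0.45 FPKM and was also below the filter. In the authors' deposited table Il10 was higher with acoustics on (log2 fold change 2.23, adjusted p = 0.0090 there). Cd86 averaged 0.53 ± 0.11 and 0.83 ± 0.38 FPKM (adjusted p = 0.45).

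Genes associated with the alternatively activated (M2) state did not rank apart (21 tested, 1 rose and 2 fell, 3 and 6 when adjusted over the list alone, camera adjusted p = 0.41). Il1rn rose, from 46.5 ± 4.795 to 197.9 ± 76.3 FPKM, and Mrc1 and Ccl24 fell. Arg1 averaged 0.45 ± 0.13 and 0.54 ± 0.26 FPKM (adjusted p = 0.78), and Tgfb1 averaged 129.1 ± 6.47 and 135.1 ± 26.4 FPKM (adjusted p = 0.87). Chemokine genes moved both ways (14 tested, 4 rose and 2 fell, 8 and 4 when adjusted over the list alone, camera adjusted p = 0.13). Without acoustics-on replicate 1, 2 rose and 3 fell, and the median log2 difference went from 1.30 to 0.31 (adjusted p = 0.45). Cxcl11 and Ccl7, which had risen with all libraries, were then below the filter and not tested. The risers Ccl2 and Ccl5 still passed, and the median was over the members still tested. With that library left out, the length and GC correction and the filter set on all libraries, 4 rose and 3 fell (median 0.91). NF-kB target genes did not rank apart (23 tested, 1 rose and 0 fell, 6 and 1 when adjusted over the list alone, camera adjusted p = 0.14). They ranked higher without acoustics-on replicate 1 (adjusted p = 0.0077) and, with no library left out, with the length and GC correction (adjusted p = 0.013).

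Matrix and matrix remodelling genes ranked higher (26 tested, 3 rose and 0 fell, 8 and 0 when adjusted over the list alone, adjusted p = 0.00038, and adjusted p = 0.15 with an estimated correlation). The members that rose included Mmp12 and the gelatinase gene Mmp9. Osteoclast genes ranked higher (16 tested, 3 rose and 0 fell, 8 and 1 when adjusted over the list alone, adjusted p = 0.0029, and adjusted p = 0.50 with an estimated correlation). Their risers were Mmp9, the acid phosphatase gene Acp5 and the kinase gene Src, of which Mmp9 is shared with the matrix list. Iron and metal handling genes ranked higher (17 tested, 3 rose and 0 fell, 5 and 1 when adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.50 with an estimated correlation), with Slc40a1, Lcn2 and the haem oxygenase gene Hmox1. Hmox1 averaged 165.9 ± 8.72 FPKM with acoustics off and 725.0 ± 338.9 with acoustics on. It is shared with the NRF2 target list, as are the ferritin genes Fth1 and Ftl1. Unfolded protein and amino acid stress genes ranked higher (36 tested, 1 rose and 0 fell, 2 and 0 when adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.73 with an estimated correlation), and the riser was Atf5. Cholesterol synthesis genes ranked higher (25 tested, 1 rose and 0 fell, 1 and 0 when adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.49 with an estimated correlation), and the riser was Acat2. Replication-dependent histone genes ranked higher (5 tested, 1 rose and 0 fell, 3 and 0 when adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.75 with an estimated correlation), and the riser was H2bc4. Without acoustics-on replicate 3, the iron and metal handling (adjusted p = 0.18) and cholesterol synthesis (adjusted p = 0.088) lists no longer passed. Without acoustics-on replicate 1, 8 matrix, 6 unfolded protein and 6 cholesterol synthesis members rose and 0 fell in each. These 3 lists still passed, and the matrix median log2 difference went from 0.26 to 0.14. The osteoclast and the iron and metal handling lists then had 3 risers each, and 1 iron and metal handling member fell.

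Macrophage identity genes ranked lower (29 tested, 0 rose and 2 fell, 0 and 6 when adjusted over the list alone, adjusted p = 0.0034, and adjusted p = 0.75 with an estimated correlation), but not without acoustics-on replicate 3 (adjusted p = 0.12). The chemokine receptor gene Ccr2 fell from 3.60 ± 0.61 to 0.90 ± 0.61 FPKM. Adgre1, which encodes the macrophage marker F4/80, averaged 247.9 ± 3.43 and 176.8 ± 60.5 FPKM and did not pass (adjusted p = 0.28). Of 23 antigen presentation genes tested, 0 rose and the class II genes H2-Aa and H2-Ab1 fell (2 and 2 when adjusted over the list alone, adjusted p = 0.20). That list ranked higher without acoustics-on replicate 3 (adjusted p = 0.024).

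A trend with transcript length was largest in acoustics-on replicates 1 and 2. Against the acoustics-off mean, the rank correlation with length across protein-coding genes was -0.55 in acoustics-on replicate 1, -0.44 in replicate 2 and 0.03 in replicate 3. It was 0.24, -0.31 and 0.05 in acoustics-off replicates 1, 2 and 3, each against the mean of the other acoustics-off libraries. Genes are not independent replicates. In replicate 1 the shortest quintile of genes had a median log2 difference of 0.55 and the longest quintile -0.58. The first principal component, with 64.4% of the variance, placed replicate 1 at 58.8 and the other acoustics-on libraries at 4.66 and 2.54. The acoustics-off libraries lay between -23.5 and -19.8 on it. On the second component, with 21.2% of the variance, acoustics-on replicate 1 lay at 13.3, beside the acoustics-off libraries at 9.35 to 10.5. Acoustics-on replicates 2 and 3 lay at -10.3 and -32.6 there. A further 4 lists in which no member passed over all genes ranked apart. Oxidative phosphorylation genes ranked higher (53 tested, 0 rose and 0 fell also when adjusted over the list alone, adjusted p = 8.8e-06, and adjusted p = 0.75 with an estimated correlation), with medians of 0.84, 0.23 and -0.03 in acoustics-on replicates 1, 2 and 3. Their median log2 difference was 0.36, and 0.12 without acoustics-on replicate 1 (adjusted p = 0.0055). DNA replication genes ranked higher (40 tested, 2 rose and 0 fell when adjusted over the list alone, adjusted p = 0.0088, and adjusted p = 0.75 with an estimated correlation). Cytosolic ribosomal protein genes ranked lower (68 tested, 0 and 0 when adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.77 with an estimated correlation), with medians of 0.17, -0.23 and -0.74. Their median log2 difference was -0.25, and -0.48 without acoustics-on replicate 1 (camera with the preset correlation, adjusted p = 2.4e-13). The correlation estimated with all libraries was 0.92 for this list, so that p-value overstates the evidence. Toll-like and NOD-like receptor signalling components ranked lower (28 tested, 0 and 0 when adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.75 with an estimated correlation). Without acoustics-on replicate 1, the DNA replication list (adjusted p = 0.16) and the receptor signalling list (adjusted p = 0.22) no longer passed. The DNA replication list did not pass without acoustics-off replicate 1 either (adjusted p = 0.052), and the ribosomal protein list did not without acoustics-on replicate 3 (adjusted p = 0.81).

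**Figure D2:**
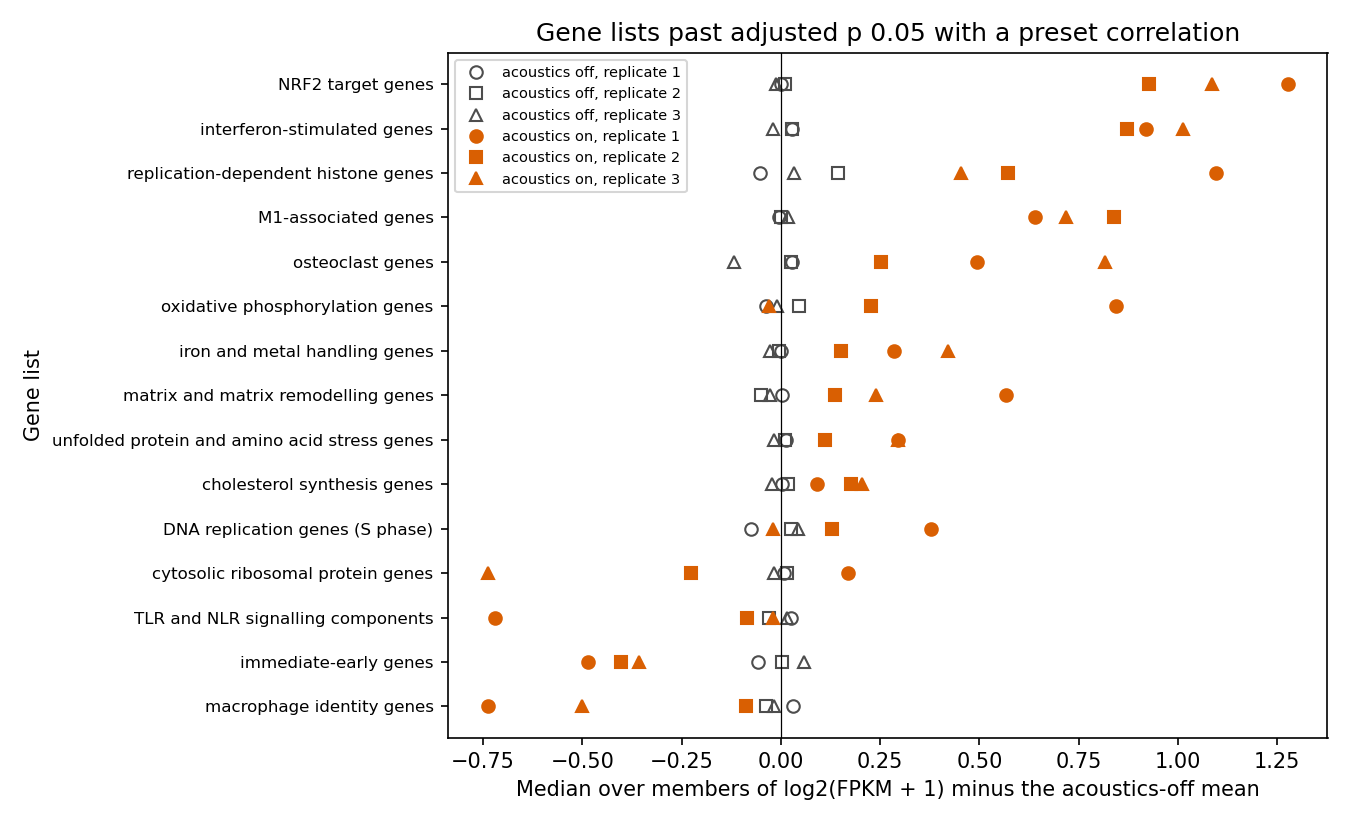
Median over list members of log2(FPKM + 1) minus the acoustics-off mean, per library, for the 15 lists past adjusted p 0.05 with a preset correlation; open grey symbols are acoustics-off and filled orange symbols acoustics-on libraries. NRF2 target genes lie between 0.93 and 1.28 in the acoustics-on libraries, while ribosomal protein genes lie between -0.74 and 0.17.

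**Figure D3:**
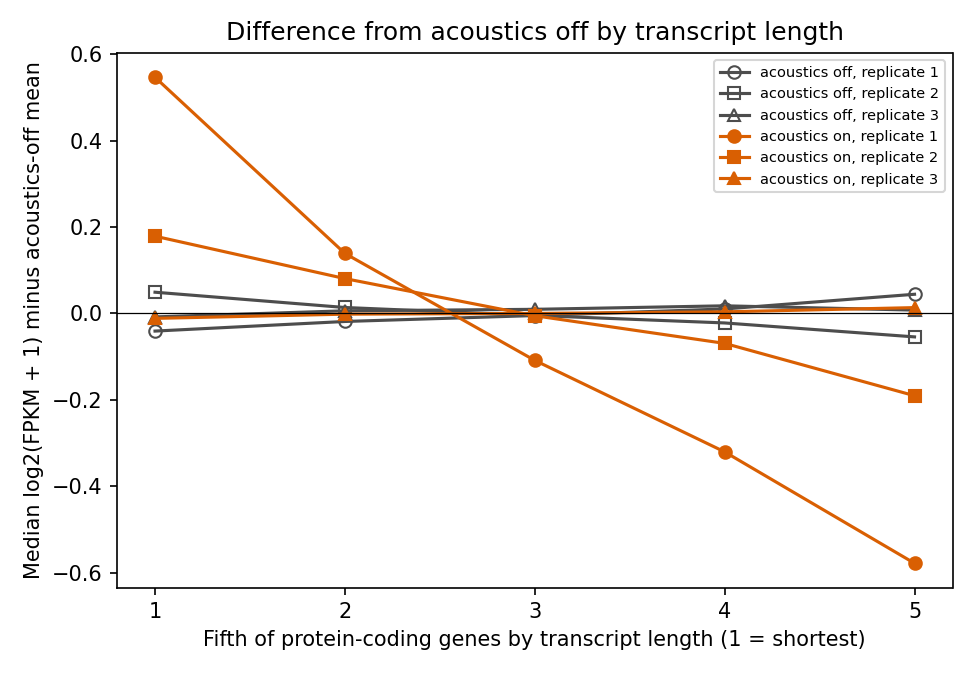
Median log2(FPKM + 1) difference from the acoustics-off mean (for an acoustics-off library, from the mean of the other acoustics-off libraries) by quintile of protein-coding genes ordered by transcript length. Acoustics-on replicate 1 runs from 0.55 in the shortest quintile to -0.58 in the longest.

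The force-sensing lists described here did not pass the list test in the main analysis. Of 19 mechanosensitive channel genes tested, the pannexin gene Panx1 rose, from 4.61 ± 0.55 to 15.6 ± 1.99 FPKM (1 and 0 when adjusted over the list alone, list adjusted p = 0.53). That list ranked higher with the length and GC correction and acoustics-on replicate 1 left out (adjusted p = 0.038, 5 rose and 0 fell). The channel gene Piezo1 (chromosome 8, 122481698 to 122551329) averaged 20.1 ± 2.16 FPKM with acoustics off and 19.6 ± 4.36 with acoustics on (log2 difference -0.06, SE 0.19, adjusted p = 0.87). No member passed over all genes among 11 YAP and TAZ target genes (2 and 0 when adjusted over the list alone, adjusted p = 0.57), 19 MRTF and SRF target genes (2 and 1, adjusted p = 0.63) and 13 integrins (6 and 3, adjusted p = 0.44). Of 29 focal adhesion components, Src rose (1 and 0, adjusted p = 0.57). Of 26 calcium and NFAT response genes, Rcan1 rose (1 and 0, adjusted p = 0.91).

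The other lists described here did not pass either. Counts are members that rose and fell over all genes, then when adjusted over the list alone. They were 0 and 0, then 0 and 0 of 18 inflammasome and pyroptosis genes (adjusted p = 0.60), and 0 and 0, then 0 and 0 of 42 mitosis genes (adjusted p = 0.27). The mitosis list ranked higher without acoustics-on replicate 3 (adjusted p = 0.046) and, with no library left out, with the length and GC correction (adjusted p = 0.040). Counts for the next lists are in the same order. They were 1 and 1, then 6 and 3 of 25 p53 target genes (adjusted p = 0.29), with Fas higher and Btg2 lower and adjusted p = 0.047 for the list without acoustics-on replicate 1, and 1 and 0, then 2 and 1 of 25 apoptosis regulators (adjusted p = 0.79), with Mlkl higher. Glycolysis genes had 0 and 1, then 1 and 1 of 24 (adjusted p = 0.63), with Hk2 lower, and hypoxia response genes had 1 and 1, then 3 and 5 of 27 (adjusted p = 0.22), with Hmox1 higher and Vegfa lower. Heat shock genes had 1 and 0, then 1 and 0 of 21 (adjusted p = 0.27), with Dnajb4 higher. Fatty acid synthesis and lipid droplet genes had 1 and 0, then 2 and 0 of 21 (adjusted p = 0.57), with Me1 higher. LXR target and lipid efflux genes had 1 and 0, then 2 and 2 of 19 (adjusted p = 0.63), and phagocytosis and scavenger receptors had 1 and 0, then 4 and 2 of 28 (adjusted p = 0.98), with Cd36 higher in both. Lysosome and autophagy genes had 1 and 0, then 3 and 0 of 44 (adjusted p = 0.57), with Sqstm1 higher. Among markers of other cell types, fibroblast markers had 1 and 0, then 1 and 1 of 4 (adjusted p = 0.42), with Pdpn higher. T cell and NK cell markers had 0 and 0, then 0 and 0 of 3 (adjusted p = 0.44), and dendritic cell markers had 0 and 0, then 0 and 2 of 6 (adjusted p = 0.51). Of 2 B cell markers tested, Ighm fell (0 and 2 when adjusted over the list alone). Neither of 2 endothelial markers (0 and 0) nor of 2 neutrophil and mast cell markers (1 and 1) passed over all genes. These last 3 lists were too short for the list test. In the calcium and NFAT, apoptosis, fatty acid, LXR and phagocytosis lists the median, the mean and the direction of the test differed in sign.

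In the authors' deposited table, 1098 genes had an adjusted p under 0.05, of which 737 were higher and 361 lower with acoustics on. Among the genes tested here, 968 passed in the authors' deposited table, and these included 238 of the 242 genes called here, with the same sign in all 238. The correlation of the log2 fold changes across genes between the authors' deposited table and the values here was 0.93. Nos2 had a log2 fold change of 5.16 in the authors' deposited table (adjusted p = 2.7e-05 there), while it did not pass in the main test here.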

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

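The length and GC corrections, the library weights and the median-ratio scaling were chosen after seeing the data. The count of 242 genes past the threshold was 150 with no filter on FPKM, where 16108 genes were tested (139 genes were in both). It ranged from 17 to 855 when each library was left out (17 without acoustics-off replicate 2, 855 without acoustics-on replicate 1), and was 26, 25, 324 and 63 without acoustics-off replicates 1 and 3 and acoustics-on replicates 2 and 3; the cause was not tested. It was 668 with the length and GC correction, 589 with its first form, and 1457 with the correction and acoustics-on replicate 1 left out; the cause was not tested. Estimated library weights gave 6526 genes, but their estimation did not converge and ran from 0.062 to 13.4, so this count is not used. Scaling to column totals gave 178 genes (145 higher, 33 lower, against 175 and 67), of which 144 were among the 242. Other settings gave 174 to 259 genes. Median-ratio scaling could move nothing, since the factors of the deposited columns were already 1 to within 4.9e-10, so it was no check. The count of lists past the threshold was 15, and was 0 with an estimated correlation and 8 with fry, 1 of which (chemokines, adjusted p = 0.023) was not among the 15. Other settings gave counts of 13 to 16 lists. Il1b, not past the threshold at a log2 difference of -0.07, turned to 0.87 without acoustics-on replicate 1 (-0.54 at the lowest, without replicate 3) and to 0.73 with the length and GC correction and that library left out; its low value in that library shows the cause. It was 0.82 with the library weights, which are not used. A change of sign is counted as a reversal only where the value passes the threshold in either setting, and by that rule no other named gene or list reversed. Some values short of the threshold did change sign, such as Piezo1 (from -0.06 to 0.19 with the length and GC correction), Tgfb1 (from 0.05 to -0.10 without acoustics-on replicate 1) and the mean of the focal adhesion list (from -0.06 to 0.02 with the correction). Over these settings, apart from the library weights and the median-ratio scaling, named genes lost a call 210 times, gained one 215 times and kept their side 2275 times; lists lost 35, gained 14 and kept 645. With the replicate number as a block, 179 genes and 16 lists passed, among them the chemokine list (adjusted p = 0.029). Same-numbered libraries did not deviate together (correlations across genes of -0.07, -0.02 and 0.00), and no library correlated best with its own number. These values give no sign that the numbers pair the samples. With so few libraries they cannot exclude a shared day or culture. The endings of the library codes match between the groups for replicates 2 and 3 but differ for replicate 1. The block thus paired acoustics-off and acoustics-on libraries that the codes do not pair for replicate 1. Of the 242 genes called here, 233 had an adjusted p under 0.01 in the authors' deposited table. Planned count-based alternatives were not run because the files hold FPKM; the scalings were applied to FPKM instead. Nos2 was not tested when any acoustics-on library was left out of the main test, since fewer than 3 libraries then reached the filter. With the length and GC correction and acoustics-on replicate 1 left out, where the filter was set on all 6 libraries, it passed (log2 difference 3.91, adjusted p = 6.0e-05).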

Other observations

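The gene families in this paragraph were picked from 14 looked at after the values were seen. Of 15 glutathione S-transferase genes tested, 6 rose and 0 fell, and all 15 had positive log2 differences with a median of 0.71. The complement genes C1qb and C1qc did not pass, with log2 differences of -3.83 (adjusted p = 0.051) and -4.06 (adjusted p = 0.061), beside C1qa, which fell. The ferritin genes Fth1 and Ftl1 did not pass either; Fth1 averaged 9441 ± 232 FPKM with acoustics off and 22171 ± 9435 with acoustics on (SD, n = 3). All 38 proteasome genes tested had positive log2 differences, with a median of 0.40 and 0 past the threshold (35 positive and a median of 0.22 after the length and GC correction), and medians of 0.74, 0.33 and 0.24 in acoustics-on replicates 1, 2 and 3. For 13 genes of the mitochondrial genome the median log2 difference was -0.36, and 0 passed.

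The tests of sequencing depth and of a mixed-up label below were chosen after the results were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split called 242 genes and the highest other split 2, and 1 split, the real one, gave as many.

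Acoustics-on replicate 1 lay apart from the other acoustics-on libraries. The mean SD over genes of its log2 differences from replicates 2 and 3 was 1.80 times the SD between replicates 2 and 3. After the length and GC trend was divided out the ratio was 1.69 (95% bootstrap interval over genes 1.63 to 1.76), which argues against that trend as the whole cause. The interval reflects the choice of genes, which are not independent, and not the spread between libraries. Its relative depth was 1.00 times the median of the other libraries, which argues against low depth. RNA quality, a different state of the cells and a separate library batch stay open, and no biological explanation was tested, since the labels give no difference within the group.

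The NRF2 target, interferon-stimulated and immediate-early lists ranked apart between the groups alongside the length trend. After the length and GC correction their medians kept 0.87, 0.84 and 0.88 of their size and the lists still passed camera with a preset correlation, which argues against the trend as the whole cause. The oxidative phosphorylation list kept 0.27 of its median (0.36 before, 0.10 after) and no longer passed (adjusted p = 0.076; in the first form of the correction it still passed, adjusted p = 0.017), so a length bias is a candidate explanation for that list. Ribosomal protein genes, also short, had 37 members that fell after the correction and 0 before it, and their median moved from -0.25 to -0.54. Without the correction it moved to -0.48 when acoustics-on replicate 1 was left out. Per library, the correction moved the list's median from 0.17 to -0.47 in acoustics-on replicate 1 and from -0.23 to -0.45 in replicate 2. In replicate 3, whose rank correlation with length was 0.03, it was -0.74 before and -0.72 after the correction. The acoustic treatment stays open as the biological explanation for the 3 lists, as do handling before lysis and any batch shared by a group, none of which was tested.

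Among 50 tested members of the M1-associated, NF-kB target and chemokine lists, 8 were lower in acoustics-on replicate 1 than in both other acoustics-on libraries by over 1 on the log2 scale: Nos2, Il1b, Ptgs2, Ccl5, Socs3, Saa3, Cd83 and Ccl7. These genes were named after their values were seen. Over all genes tested 457 were lower in it by that bound (3.92%, against 16.0% of the members) and 140 higher, among them Ccl2 and Ccl4. The median difference of the 8 genes was -2.36 before and -2.54 after the length and GC correction. The correction shifted this difference by -0.68 to 0.66 in the middle 95% of genes. The 8 genes lay between -3.55 and -1.51 after it. Because they were picked for large differences, a shift of 0.66 would still leave their median at -1.70. The corrected median could thus hardly have come out otherwise and is no separate test. These values show only that the trend was smaller than the differences of the picked genes. The NRF2 and interferon-stimulated medians in replicate 1 were at least 1.06 times the lower of those in replicates 2 and 3. This argues against a swapped acoustics-off label. On the second principal component, though, replicate 1 lay beside the acoustics-off libraries (13.3, against 9.35 to 10.5). A difference between the cultures and one in RNA quality or library batch stay open, and no biological explanation was tested.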
